A study of Mus musculus with 6 samples.

How the data were processed

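Gene expression was measured on Affymetrix mouse gene arrays in 6 samples of sorted pre-granulocyte-macrophage progenitors (PreGMs), 3 from mice labelled Cebpa flox/flox and 3 from mice labelled Cebpa flox/flox;Mx1Cre. Per the labels' protocols, all mice had received pIC (polyinosinic-polycytidylic acid), which switches on the Mx1 promoter and so the Cre recombinase in carriers. Bone marrow was taken on day 18, enriched for Kit-positive cells and sorted. A small amount of total RNA was amplified with a whole-transcriptome kit before biotin labelling. Each sample is 1 array, and the design text gives 3 mice per genotype, so replicates are separate mice. No processing batch or scan date was used here.

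The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA and the affy software, and RMA by its definition corrects background, quantile normalizes across arrays and summarises the probes of a set on the log2 scale. Versions, and the chip definition used, are not given in the sources used here. The deposited log2 values were not centred per gene, and their medians over all probe sets lay between 6.43 and 6.55 on the 6 arrays. RMA pulls dim probe sets towards a common floor, so folds of dim genes tend to be understated. No detection call was used here. As a guide to level, the lower quartile of the mean log2 value over genes was 5.63, the median 6.64 and the upper quartile 8.07. The number of arrays limits the precision.

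The value table held 34760 probe sets. The platform annotation, which can be old, gave a single gene symbol for 21640 of them, several symbols for 1321 and none here for 11799. Of the 21640, 21553 were found in the mouse reference gene table by their Entrez number, which changed 0 symbols, and the others kept the annotation's symbol. Where a gene had several probe sets, as 954 genes did, the set with the highest mean over all 6 arrays stood for it, giving 19937 genes. No coordinates are given because the annotation names no genome build. Probe positions within Cebpa were not used here, so it is not known whether the probe set reads the deleted part of the gene.

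Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no weights, no replicate term) and adjusted over all genes with the Benjamini-Hochberg method. A gene is called at an adjusted p under 0.05. Differences are the value in the arrays labelled Mx1Cre minus that in the arrays labelled flox/flox, with limma's moderated standard error (SE). Gene lists, 27 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Each was tested again with an estimated correlation, and with fry, which asks whether a list moves on balance one way without comparing it with other genes. The lists, the comparison, the main test and the alternatives were fixed before the data were examined. Members without a probe set of their own in the gene rows were not analysed here.

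The named genes were chosen by a rule fixed at the same time. It takes Cebpa, the 12 highest and 12 lowest called genes whose 3 values in each group do not overlap, up to 2 higher and 2 lower called members of each list, all measured sort gate and C/EBP family genes, and a few receptors and transcription factors whatever their p. Provisional gene names, olfactory receptors and the like were counted but not named. Genes named outside the rule are said to be so.

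The gene test was tested on simulated data with the real gene means and residual spreads over 19937 genes. It recovered 43.3% of 67 genes changed by 0.5 log2 units, 92.5% of 67 changed by 1 and 98.5% of 66 changed by 2, with 8 false calls among 164. A list shifted by 0.5 was the only list called. With no change, 0 genes and 0 lists were called, but those simulated genes were independent, unlike real ones. The alternatives tried were the replicate number as a block, leaving out each array, median centring, cyclic loess, 2 filters on dim genes, 2 other ways of choosing a gene's probe set, an intensity trend with a robust prior, array weights, a plain Welch test, other thresholds and the other list tests. A limma fit over all probe sets, in place of the gene rows, was added after seeing the data.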

Results

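The study set PreGMs of Cebpa flox/flox mice against PreGMs of Cebpa flox/flox mice carrying Mx1Cre, to see how the progenitor transcriptome changes when Cebpa is deleted. Cebpa encodes C/EBPα, a transcription factor that granulocyte-macrophage progenitors need in order to form. PreGMs are myeloid progenitors that precede that stage. They were sorted from bone marrow as lineage-negative, Sca1-negative, Kit-positive cells without CD150, CD41, FcγRII or endoglin. Each genotype label had 3 arrays, and all 6 mice had been injected with pIC 18 days earlier. Every array gave a log2 value for 34760 probe sets, which were reduced to 19937 genes. Array values correlated across genes at 0.992 to 0.995 within a label and at 0.984 to 0.990 between labels. Genes are not independent replicates. The first principal component carried 51.1% of the variance and placed the 3 arrays of each label on opposite sides.

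Cebpa itself ran against the genotype labels. Its level was 6.83 ± 0.11 (SD, n = 3) in the arrays labelled flox/flox and 9.0 ± 0.30 (SD, n = 3) in those labelled Mx1Cre. The difference was 2.17 ± 0.14 log2 units (SE), or 4.50-fold higher in the arrays labelled Mx1Cre, with a limma adjusted p of 2.65e-05. Over the alternatives that p ran from 3.81e-06 to 0.270, the latter where each gene's spread came from its own values alone. The flox/flox arrays read 6.93, 6.71 and 6.85 for replicates 1, 2 and 3, and the Mx1Cre arrays 8.71, 9.31 and 8.98, so the groups did not overlap. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. A deletion would lower the transcript where the probes lie in the deleted part, and their position was not used here. All directions below follow the labels as deposited, and each would turn if the labels of the groups were exchanged.

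**Figure D1:**
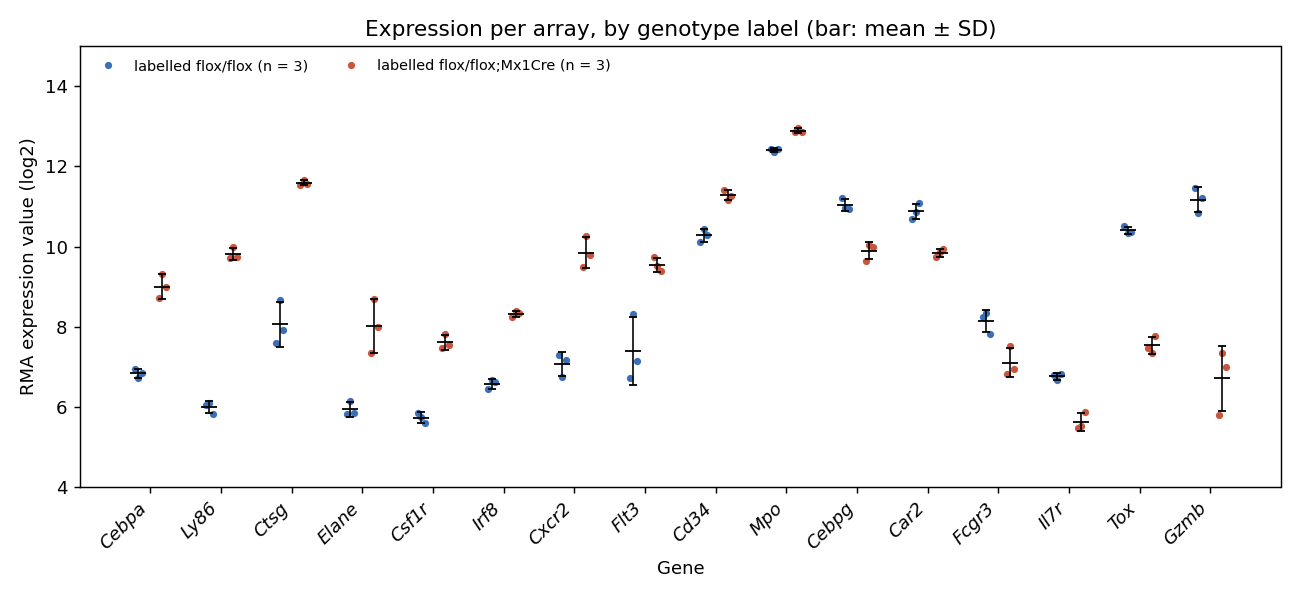
RMA expression values (log2, y axis) of 16 genes (x axis) on each array, in blue for arrays labelled flox/flox and red for arrays labelled Mx1Cre. Black bars give the mean ± SD of 3 arrays. Cebpa averages 6.83 in the arrays labelled flox/flox and 9.0 in those labelled Mx1Cre, and Gzmb averages 11.2 and 6.71.

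Granulocyte, monocyte and cell cycle genes were higher, and erythroid, megakaryocyte, T and NK cell and interferon response genes lower, in the arrays labelled Mx1Cre, by lists fixed in advance and tested with camera at its preset correlation. None of the 27 lists passed with an estimated correlation, where the smallest value was adjusted p = 0.125. That version has few degrees of freedom in so small a design, hence little power, and its failures are not all due to correlation. Growth factor receptor genes had an estimated correlation of -0.00947, below the preset 0.01, yet their camera adjusted p went from 1.13e-05 to 0.125. Of the lists named, the cell cycle, erythroid and interferon response lists did not pass with fry (adjusted p 0.0879, 0.0778 and 0.151). Of 19937 genes, 979 differed at an adjusted p under 0.05 (limma), 525 higher and 454 lower in those arrays. Changes of 2-fold or more were found for 163 genes, 95 higher and 68 lower, and for 153 to 182 genes when 1 array was left out. The count of all genes changed fell to between 538 and 785 without 1 array, where fewer arrays also lower the power. It was 541 without flox/flox replicate 1, 547 without flox/flox replicate 3, 636 without Mx1Cre replicate 2 and 538 without Mx1Cre replicate 3. In that order the higher genes numbered 298, 321, 318 and 268. The lower genes numbered 243 without flox/flox replicate 1, 226 without flox/flox replicate 3, 296 without Mx1Cre replicate 1 and 270 without Mx1Cre replicate 3. A test that took each gene's spread from its own values alone called 0 genes (2124 at an unadjusted p under 0.05, against 3276 with limma). With all 34760 probe sets in the limma fit, an alternative chosen after seeing the data, 244 of the genes passed, 141 higher and 103 lower. The values of the groups did not overlap for 21.6% of genes, where chance gives 10%.

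The 12 genes with the largest rises included Ly86, Ms4a6c and F13a1 of the monocyte and macrophage list. Ly86, a partner of a Toll-like receptor family member on myeloid cells, was higher by 3.83 ± 0.11 log2 units (SE, limma adjusted p = 1.59e-07). Ms4a6c, one of a family of similar genes whose probes can cross-react, was 12.2-fold higher, and Ctsg, the primary granule protease cathepsin G, 11.6-fold. Emb, which encodes the membrane glycoprotein embigin, was 11.0-fold higher but spread widely in the arrays labelled flox/flox (7.61 ± 0.99, SD, n = 3). Anxa3, an annexin, was 9.09-fold higher and Tfec, a transcription factor of the MiT family, 8.36-fold. S100a9 and S100a8, the calprotectin subunits of neutrophils and monocytes, were 7.36-fold and 5.98-fold higher. The chemokine receptor gene Cxcr2, the coagulation factor gene F13a1, the basophil protease gene Mcpt8 and Igsf6 were 6.32-fold to 6.89-fold higher. Adjusted p-values of these 12 genes were at most 0.000627 (limma).

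**Figure D2:**
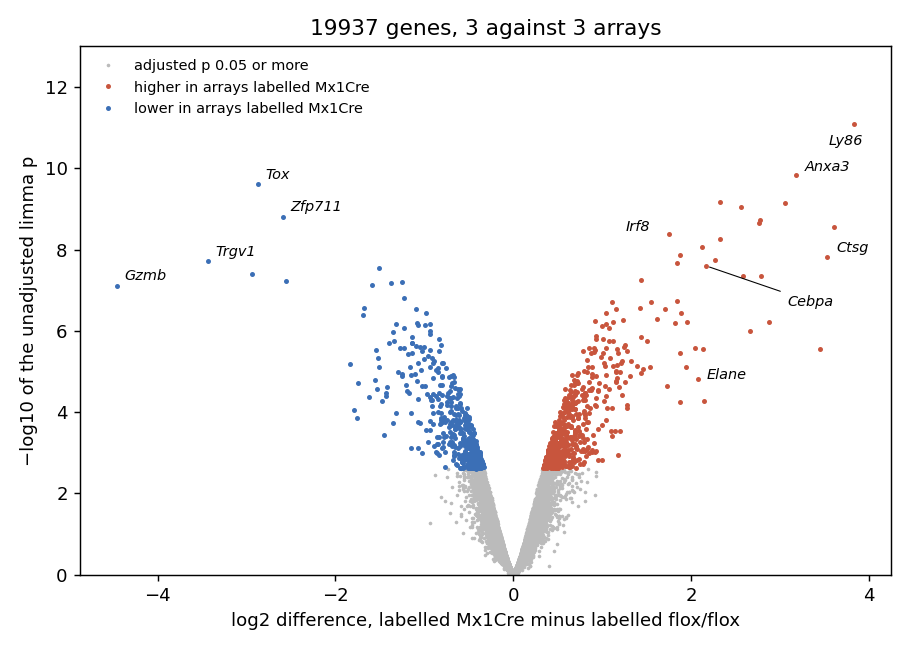
The log2 difference of each of 19937 genes, labelled Mx1Cre minus labelled flox/flox (x axis), against −log10 of the unadjusted limma p (y axis). Red and blue points are the 525 higher and 454 lower genes, grey points did not pass, and the extremes are Ly86 at 3.83 and Gzmb at -4.45.

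The 12 genes with the largest falls included Gzmb and Trat1 of the T and NK cell list, of which 21 of 26 members did not pass. Gzmb, the protease granzyme B, was 21.9-fold lower in the arrays labelled Mx1Cre (-4.45 ± 0.33 log2 units, SE, limma adjusted p = 5.39e-05), falling from 11.2 ± 0.32 to 6.71 ± 0.81 (SD, n = 3 each). Trgv1, a variable segment of the T cell receptor γ locus, was 10.8-fold lower. Tox, a transcription factor of developing T cells and innate lymphoid cells, was 7.32-fold lower and Trat1, a T cell receptor adaptor, 5.89-fold. Gzmc and Klrb1b, which like Gzmb belong to families of similar genes whose probes can cross-react, were 3.57-fold and 3.09-fold lower. Trat1, Gzmc and Klrb1b averaged 6.52, 6.56 and 6.67 in the arrays labelled flox/flox, near the median level of 6.64. In those labelled Mx1Cre they averaged 3.96, 4.72 and 5.04, below the lower quartile of 5.63. Scin, an actin-severing protein, was 7.68-fold lower and Zfp711, a zinc finger gene, 6.03-fold. Itm2a, Fcer1a (the α chain of the high-affinity IgE receptor), Prkca (protein kinase C α) and Lilr4b were 3.20-fold to 3.46-fold lower. Adjusted p-values of these 12 genes were at most 0.00805 (limma).

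Of 27 primary granule and neutrophil progenitor genes 12 rose in the arrays labelled Mx1Cre, 1 fell and 14 did not pass. Adjusted over the list alone, 16 rose and 4 fell. Clec12a, a myeloid inhibitory lectin, rose 5.90-fold and Elane, neutrophil elastase, 4.23-fold. Csf3r, the G-CSF receptor, rose 1.94-fold. Mpo, myeloperoxidase, was already bright and rose 1.39-fold, from 12.4 ± 0.042 to 12.9 ± 0.063 (SD, n = 3 each). The member that fell was Fcgr3, a low-affinity IgG receptor (2.06-fold). The list's median was 0.40 log2 units and camera gave an adjusted p of 2.43e-10, but adjusted p = 0.174 with an estimated correlation.

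Secondary granule and mature neutrophil genes showed 8 of 24 members higher and 0 lower (11 and 0 adjusted over the list alone), led by Cxcr2, S100a8 and S100a9. The other 16 did not pass. Outside the naming rule, these included Ltf, Camp, Mmp8 and Mmp9 (0.27, 0.43, 0.40 and -0.01 log2 units). Ngp, Lcn2 and Chil3, also outside the rule, rose from dim levels of 5.66, 5.57 and 4.48 to 6.56, 6.16 and 5.40. This list's camera adjusted p was 1.83e-07, and adjusted p = 0.175 with an estimated correlation. Of 27 monocyte and macrophage genes 14 rose and 0 fell, the same counts as when adjusted over the list alone. Beside Ly86, Ms4a6c and F13a1 they included Mpeg1, which encodes the pore-forming protein perforin-2 (2.32 log2 units), Csf1r, the M-CSF receptor (3.67-fold), and Irf8, a transcription factor of monocyte and dendritic cell development (3.37-fold). The list's camera adjusted p was 1.47e-15, and adjusted p = 0.125 with an estimated correlation. Dendritic cell genes were mixed. Flt3, a cytokine receptor of early progenitors, and H2-DMa rose 4.43-fold and 2.25-fold, while Id2 and Cd7 fell 2.03-fold and 1.58-fold. Of 23, 3 rose and 2 fell (8 and 3 adjusted over the list alone). That list's camera adjusted p of 0.0208 became adjusted p = 0.394 with an estimated correlation. It was 0.122 without flox/flox replicate 3, 0.161 among genes above the median level and 0.0664 among genes above the lower quartile.

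Of 26 growth factor receptor genes 7 rose, 1 fell and 18 did not pass (11 rising and 1 falling adjusted over the list alone). Csf1r, Flt3, Csf3r and Ifngr2, an interferon-γ receptor chain (3.07-fold), were among those that rose, and Il7r, the interleukin-7 receptor of lymphoid progenitors, fell 2.19-fold. The camera adjusted p was 1.13e-05, and adjusted p = 0.125 with an estimated correlation. Csf2rb, Il6ra, Csf2ra and Kit did not pass, with differences of 0.44, 0.37, 0.25 and 0.15 log2 units (limma adjusted p 0.117, 0.0890, 0.274 and 0.513).

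Among 8 measured C/EBP family genes and their regulators, Cebpa and Cebpd rose and Cebpg fell. Cebpg, a family member that lacks a transactivation domain, was 2.20-fold lower (11.0 ± 0.15 against 9.89 ± 0.22, SD, n = 3 each, limma adjusted p = 0.000692). Cebpd was 1.35-fold higher, with an adjusted p of 0.0274 (limma). Cebpe, Trib1, Trib2, Cebpb and Ddit3 did not pass, with differences of 0.32, -0.03, -0.09, -0.21 and -0.33 log2 units. Cebpb passed without Mx1Cre replicate 2, at -0.44 (0.0498, in a range over the alternatives of 0.0498 to 0.883). Adjusted over the list alone, 3 rose and 2 fell. The list showed no common shift (camera adjusted p = 0.609). Its median of -0.06 and mean of 0.14 differ in sign.

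Of 51 haematopoietic transcription factors 5 rose and 6 fell (8 and 11 adjusted over the list alone), with a camera adjusted p of 0.609. Irf8 and Hlf, a stem cell factor (1.89-fold), rose, and Stat3 (1.51-fold), Id2 and Gata3 (1.41-fold), a T cell and innate lymphoid factor, fell. Spi1, the myeloid factor PU.1, lay just outside the threshold at 0.50 ± 0.12 log2 units (SE, limma adjusted p = 0.0502), and passed without flox/flox replicate 1 (0.0166, in a range over the alternatives of 0.0166 to 0.447). It also passed with cyclic loess, both filters on dim genes, the intensity trend, array weights and, barely, the mean of probe sets. Gfi1, Gata2 and Gata1 did not pass, with differences of 0.18, -0.21 and -0.49 log2 units. Stem and multipotent progenitor genes split evenly, 5 of 36 rising and 5 falling (8 and 6 adjusted over the list alone, camera adjusted p = 0.456). Cd34, the progenitor surface antigen, rose 2.01-fold, whereas Ifitm1 fell 2.25-fold and Angpt1 1.49-fold.

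Of 32 erythroid genes 7 fell in the arrays labelled Mx1Cre and 0 rose (11 and 1 adjusted over the list alone), among them Car2, carbonic anhydrase 2 (2.04-fold), and Hemgn, hemogen (1.88-fold). Camera's adjusted p was 4.06e-07, and adjusted p = 0.247 with an estimated correlation. Of 23 megakaryocyte and platelet genes 6 fell and 1 rose (10 and 2 adjusted over the list alone). Ppbp, a platelet chemokine, fell 2.50-fold (from 6.67 to 5.35, below the lower quartile of levels) and F2r, a thrombin receptor, 1.79-fold, whereas Mef2c, also a lymphoid factor, rose 1.78-fold. The camera adjusted p was 3.14e-05, and adjusted p = 0.125 with an estimated correlation.

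Mast cell and basophil genes went both ways, 4 of 23 higher and 7 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.230). Mcpt8 and Hgf, hepatocyte growth factor (2.07-fold), rose, and Gzmb, Cyp11a1 (2.35-fold) and Fcer1a fell. Of 26 T and NK cell genes 5 fell and 0 rose (9 and 1 adjusted over the list alone). Gzmb and Trat1 led them, and Cd3e, a chain common to T cells, differed by -0.003 ± 0.085 log2 units (SE). For the list, camera's adjusted p of 0.000119 became adjusted p = 0.175 with an estimated correlation. Of 27 B lymphoid genes only Il7r fell and 0 rose (2 and 0 adjusted over the list alone). That list's camera adjusted p of 0.0208 became adjusted p = 0.296 with an estimated correlation. It was 0.110 without flox/flox replicate 2 and 0.171 among genes above the median level.

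None of 10 eosinophil genes and 9 plasma cell genes passed, over all genes or over the list alone (camera adjusted p 0.698 and 0.948). The eosinophil members of smallest p were Cebpe and Gata1, and the plasma cell members Jchain and Sdc1, with differences of -0.29 and 0.20 log2 units. The plasma cell list's median (-0.03) and mean (-0.01) were opposite in sign to its camera test. Of 23 stromal and endothelial genes only Pdgfrb fell (1.46-fold) and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.250). Of the 14 measured genes of the sort gate list, Cd34 and Fcgr2b (1.34-fold) rose, and Fcgr3 and Il7r fell (2 rising and 4 falling adjusted over the list alone). The gate as described above does not name the products of Cd34 and Il7r. The sort gate list did not pass with camera (adjusted p = 0.403) but passed with fry, downwards (adjusted p = 0.0159). It mixes the selected Kit with excluded antigens, so its common direction does not describe the gate. Of the excluded antigens, FcγRII is encoded by Fcgr2b, which passed (0.43 log2 units, limma adjusted p = 0.0410). Slamf1, Itga2b and Eng, which encode the excluded CD150, CD41 and endoglin, did not pass, at -0.17, -0.33 and -0.05 log2 units. Itgam, Ly6g, Cd4, Cd8a and Ptprc did not pass either, with differences between -0.26 and 0.23.

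**Figure D3:**
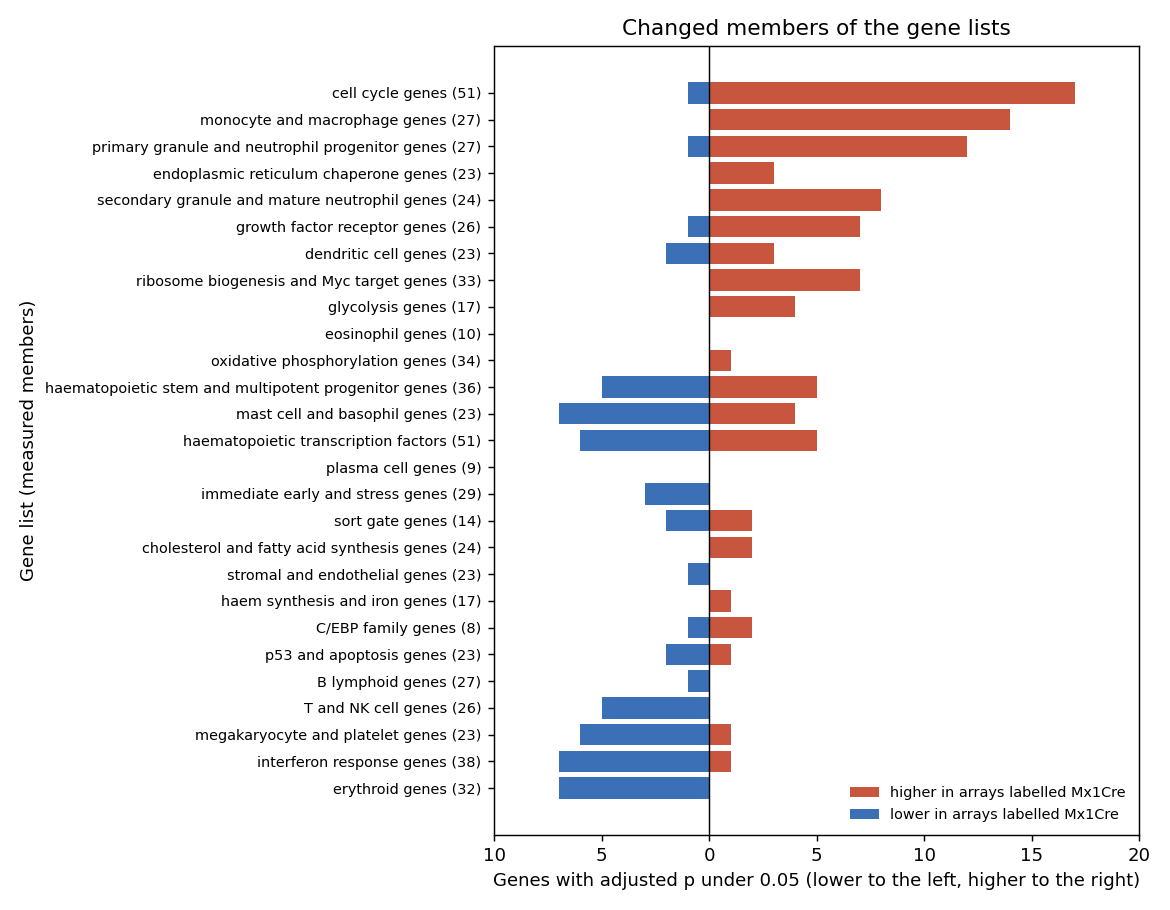
Number of members with a limma adjusted p under 0.05 (x axis) in each of 27 gene lists (y axis, measured members in parentheses, ordered by the list's median difference). Red bars to the right are genes higher, and blue bars to the left genes lower, in the arrays labelled Mx1Cre, reaching 17 for the cell cycle list and 7 for the erythroid list.

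Of 51 cell cycle genes 17 rose in the arrays labelled Mx1Cre and 1 fell, and 32 rose and 1 fell when adjusted over the list alone. Ccnd1, cyclin D1, rose 2.13-fold and Uhrf1, a maintenance methylation factor of S phase, 1.61-fold. The member that fell was Cdkn1b, the cell cycle inhibitor p27 (1.36-fold). The median was 0.44 log2 units. The camera adjusted p of 3.26e-18 became adjusted p = 0.296 with an estimated correlation. That correlation was 0.672 across arrays within a label, and the low power of that version adds to the loss.

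Of 33 ribosome biogenesis and Myc target genes 7 rose and 0 fell (10 and 0 adjusted over the list alone), including Polr1a (1.56-fold) and Utp20 (1.49-fold). Camera's adjusted p was 1.18e-09, and adjusted p = 0.175 with an estimated correlation. Of 17 glycolysis genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), led by Pfkp, a phosphofructokinase (2.25-fold), and Hk2, a hexokinase (1.74-fold). Their camera adjusted p was 9.02e-05, and adjusted p = 0.174 with an estimated correlation. Of 23 genes of the endoplasmic reticulum chaperone list 3 rose and 0 fell (6 and 1 adjusted over the list alone). They included Pdia6 at 1.54-fold and Asns, which encodes asparagine synthetase and not a chaperone, at 1.43-fold. Their camera adjusted p was 1.67e-05, and adjusted p = 0.341 with an estimated correlation. Of 34 oxidative phosphorylation genes Uqcrq alone rose (1.30-fold) and 0 fell, with 0 passing over the list alone. That list's camera adjusted p of 0.000499 became adjusted p = 0.557 with an estimated correlation, and 0.105 without flox/flox replicate 1. Of 24 cholesterol and fatty acid synthesis genes Acaca (1.48-fold) and Fasn (1.31-fold) rose and 0 fell (2 and 0 adjusted over the list alone). Of 17 haem synthesis and iron genes only Alas1 passed, rising 2.01-fold (1 adjusted over the list alone). Neither list shifted (camera adjusted p 0.948 and 0.615), and the median of the cholesterol list, -0.04, and its mean, -0.0025, were opposite in sign to its test.

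Of 38 interferon response genes 7 fell in the arrays labelled Mx1Cre and 1 rose (11 and 2 adjusted over the list alone). Rtp4 fell 2.79-fold and Usp18, a negative regulator of interferon signalling, 2.30-fold. Gbp3, a guanylate-binding protein, rose 2.93-fold. The camera adjusted p was 1.7e-05, and adjusted p = 0.341 with an estimated correlation. Of 23 p53 and apoptosis genes 1 rose and 2 fell (1 and 5 adjusted over the list alone). Bcl2, which opposes apoptosis, rose 1.72-fold, and the stress genes Trp53inp1 and Gadd45a fell 2.38-fold and 1.69-fold. For the list, camera's adjusted p was 0.0402, adjusted p = 0.237 with an estimated correlation. Without flox/flox replicate 1, flox/flox replicate 3 or Mx1Cre replicate 1 it was 0.0675, 0.162 and 0.0507, and 0.0554 among genes above the lower quartile. Of 29 immediate early and stress genes 3 fell and 0 rose (5 and 1 adjusted over the list alone), led by Btg2 (2.14-fold) and Ier3 (1.96-fold). The camera adjusted p was 0.0294, adjusted p = 0.175 with an estimated correlation. Without Mx1Cre replicate 2 or 3 it was 0.0862 and 0.0529.

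In all, 17 of 27 lists passed with camera at the preset correlation, 10 higher and 7 lower, and 0 with an estimated correlation. Fry passed 11 lists, 10 of them among those 17. The 7 lists that passed with camera and not with fry were dendritic cell (fry adjusted p 0.193), erythroid (0.0778), B lymphoid (0.0584), interferon response (0.151), cell cycle (0.0879), oxidative phosphorylation (0.287) and endoplasmic reticulum chaperone genes (0.120). In the 9 other splits of the 6 arrays into 3 and 3, camera at the preset correlation passed 3 to 11 lists. Those splits keep part of the label difference, so these counts are not a rate under no difference. Of the 77 called named genes, 11 lost the call without some single array. Fasn, Uqcrq and Cdkn1b lost it without each of the 6 arrays in turn, with adjusted p-values (limma) up to 0.124, 0.154 and 0.109. Cebpd and Fcgr2b lost it without each array but Mx1Cre replicate 1 (up to 0.118 and 0.147). Asns lost it without flox/flox replicate 1 or 2 or Mx1Cre replicate 2 or 3 (up to 0.141), and Pdia6 without any flox/flox array or Mx1Cre replicate 3 (up to 0.0895). Id2 lost it without any flox/flox array (up to 0.0969), Cd7 without flox/flox replicate 2 or Mx1Cre replicate 1 or 3 (up to 0.0676), Stat3 without flox/flox replicate 1 or 3 (up to 0.0579) and Gata3 without flox/flox replicate 3 (0.0503). Median centring also ended the calls of Asns (0.0586) and Fcgr2b (0.0587), and averaging probe sets that of Cdkn1b (0.0901). With all probe sets in the fit 54 of the 77 named genes passed. The 23 others were those 11 and Flt3, Hlf, Mpo, Pdgfrb, Angpt1, Ier3, Fcgr3, Ifitm1, Rtp4, Klrb1b, Fcer1a and Itm2a, whose adjusted p-values (limma) lay between 0.0523 for Angpt1 and 0.110 for Fcgr3.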

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

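Probe sets left out of the gene comparison, because they have several gene symbols or none here, held few differences between the labels, and they are listed only because no comparison used them. Of these 13120 probe sets, 45 passed an adjusted p under 0.05 in a limma fit over all 34760 probe sets, 20 of them higher in the arrays labelled Mx1Cre. That is 0.343% of them, against 1.19% (257) of the 21640 probe sets with a single symbol in that fit. Those with several symbols gave 9 of 1321 and those with no symbol 36 of 11799.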

How the results depend on the processing

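Of the 77 called named genes, Cebpa included, 77 kept their direction in every alternative that held them. Leaving out 1 array gave 538 to 785 genes changed, 268 to 455 higher and 226 to 359 lower in the arrays labelled Mx1Cre, with fewer arrays tested, and left the Cebpa difference between 2.02 and 2.32. The Welch test gave 0 genes changed, 0 higher, 0 lower and 0 by 2-fold or more, with a smallest adjusted p of 0.0568, because it estimates each gene's spread from its own 3 values. Cebpa kept its 2.17 there, at an adjusted p of 0.270. A threshold of 0.01 gave 389 genes changed and one of 0.1 gave 1466. Of the 27 gene lists, 0 passed with an estimated correlation and 11 with fry, 10 of them among the 17 gene lists shifted and 1, the sort gate genes, with fry alone (down, adjusted p = 0.0159). The main test, fixed in advance, did not take the replicate numbers to pair the arrays, and the values do not settle whether they do. Deviations of same-numbered arrays correlated at 0.188, 0.0515 and 0.174, and those of differently numbered arrays across the labels at -0.245 to 0.124. By these deviations Mx1Cre replicates 1 and 3 lay closest to the flox/flox array of their number, but Mx1Cre replicate 2 to flox/flox replicate 3. By the values themselves Mx1Cre replicate 1 correlated least with flox/flox replicate 1 (0.9847) and most with flox/flox replicate 2 (0.9875). With the replicate block 1089 genes changed. A limma fit over all 34760 probe sets, chosen after seeing the data, gave 244 genes changed, 141 higher and 103 lower, all 244 among the 979, and left Cebpa at an adjusted p of 0.00514. It tests more rows, and its prior had 2.72 degrees of freedom, against 6.10 over gene rows. The other settings at the 0.05 threshold gave 861 (median centring) to 1389 (array weights) genes changed. Signs turned only for results that passed no test, and the cause was not tested. Leaving out 1 array, the ranges were -0.0369 to 0.0274 for Cd3e, -0.131 to 0.105 for Ly6g, -0.184 to 0.0732 for Trib1, -0.224 to 0.0759 for Trib2 and -0.111 to 0.0209 for Eng. List medians ran from -0.0543 to 0.0086 for mast cell and basophil genes, -0.098 to 0.041 for plasma cell genes, -0.204 to 0.0746 for C/EBP family genes and -0.0819 to 0.0302 for cholesterol and fatty acid synthesis genes. Cyclic loess gave 0.010 for Cd3e and 0.0192 for mast cell and basophil genes, array weights 0.0020 for Ly6g, the median-level filter -0.0329 for haematopoietic stem and multipotent progenitor genes, and the quartile filter 0.0016 for haematopoietic transcription factors. Dim genes are limited by signal over background, which has no measure here.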

Other observations

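The tests of the label, sex and lymphocyte patterns below were chosen after the results were seen, and the counts over other splits of the arrays were planned. The genes of the first paragraphs were chosen after their values were seen. Of the Ms4a family of membrane proteins, which was not a fixed list and was not tested as a group, Ms4a6c, Ms4a3, Ms4a6b and Ms4a4c were 3.61, 1.87, 1.82 and 1.73 log2 units higher in the arrays labelled Mx1Cre (limma adjusted p 5.52e-06, 0.00425, 0.000255 and 0.00237). Ms4a2, of the mast cell and basophil list, was also higher, by 1.28 (limma adjusted p = 0.00529). Some members did not pass, such as Ms4a1 and Ms4a6d, with differences of 0.26 and 0.31 (adjusted p 0.476 and 0.221). The members are similar in sequence and probes can cross-react. Other high genes were Met, the hepatocyte growth factor receptor (2.33), whose ligand gene Hgf was also higher, Ccl9, a myeloid chemokine (2.27), Hk3, a myeloid hexokinase (2.12), and Hpse, heparanase (1.85).

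Of the fixed T and NK cell genes 21 of 26 did not pass. Some single genes known from lymphocytes, picked by hand and not tested as a group, were lower in the arrays labelled Mx1Cre. Lag3, an inhibitory receptor, differed by -1.52 log2 units, Ctsw, a protease of cytotoxic cells, by -1.54, Lat, an adaptor of T cells and mast cells, by -1.40, and Prkcq, a protein kinase C of T cells, by -1.42, with limma adjusted p-values of 0.000846, 0.000636, 0.00054 and 0.00251. Rora, a factor of innate lymphoid cells, differed by -1.36 (adjusted p = 0.000343). Dntt, an early lymphoid gene, was bright under both labels and differed by 0.02 (adjusted p = 0.983).

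Cebpa was higher, not lower, in the arrays labelled Mx1Cre. A single wrong array label is argued against by the gap of 1.77 log2 units between the groups' Cebpa values, against a widest range of 0.602 within a group. That the labels are right and the probe set only reads outside the deleted part would leave Cebpa alike under both labels, which its difference of 2.17 (95% interval 1.86 to 2.49) argues against. A rise of a leftover transcript in carriers was not tested directly. A candidate explanation is that the genotype labels of the groups were exchanged at some step. Of the measured members of the 3 myeloid lists, 74% (57 of 77) were lower in the arrays with low Cebpa. Of the 35 called members 34 were, with a median difference of 1.70 and Fcgr3 as the exception, while over all 77 the median was 0.40 and the lower quartile -0.01. These shares cannot tell exchanged labels from right labels with a working Cebpa transcript, because myeloid genes can follow its level under either. A leftover transcript that makes no working C/EBPα gives no reason for myeloid genes to rise. The 57 of 77 members, and fry passing all 3 lists upwards (adjusted p 0.0127, 0.0159 and 0.0031), argue against it for these genes.

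The sex in the labels also stands against the values. The labels call all the mice female, yet the Y-linked genes Kdm5d, Uty and Eif2s3y averaged 9.18, 8.27 and 8.94 over the 6 arrays and never fell below 7.92, while Xist, the transcript of the inactive X chromosome, lay between 4.81 and 5.41. Xist exceeded only 14% of genes, which argues against female mice whose Y-linked probe sets read the X-linked copies. These values are consistent with male mice on all 6 arrays. Xist rests on a single probe set, and none of the 4 genes passed the threshold between the labels (limma adjusted p 0.0755 to 0.747).

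Gzmb, Trgv1, Tox and Trat1 were far higher in the arrays labelled flox/flox, where Cebpa was low, though Trat1 averaged only 6.52 there. T or NK cells carried through the sort, which removed lineage-positive cells, stay open. The 24 members of their list without Gzmb and Trat1 had a median difference of -0.117 (quartiles -0.366 and -0.0272), but 3 fell past the threshold, Ccl5 (-1.53), Cd96 (-1.23) and Gata3 (-0.49), and 0 rose. Mast cells or basophils stay open, although a gate of Kit-positive cells without FcγRII would remove basophils, which lack Kit, and mast cells that carry FcγRII, because the 22 members of their list without Gzmb went both ways, 4 rising and 6 falling past the threshold (median -0.00198, lower quartile -0.659). Also open, and untested, are that progenitors with little Cebpa express part of a lymphoid programme, or that another progenitor fills the gate.

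The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For each count only 1 split, the real one, reached the value found. Every other split mixes the labels within its groups, so the label difference widens the spread there and lowers the gene calls by construction. The real split gave 979 genes, 525 higher, 454 lower and 163 by 2-fold or more, and the highest of the others was 0 for each. It gave 17 lists, and the highest of the others was 11. The other splits also keep part of the label difference between their groups, so their list counts do not show how many lists pass with no difference.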
